A study of Mus musculus with 10 samples.

How the data were processed

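Gene expression was measured by RNA sequencing in cultures of 2 mouse melanoma cell lines, D4M.3A and B16/F10, in which Xrn1 had been targeted or not. Xrn1 encodes the main cytoplasmic exoribonuclease that degrades decapped RNA from its 5' end. The 10 libraries form 5 sets, each of 1 library labelled as Xrn1-silenced and 1 control library of the same cell line and technique. D4M.3A was studied with an shRNA set and an sgRNA (CRISPR/Cas9) set, and B16/F10 with siRNA, shRNA and sgRNA sets. The shRNA and sgRNA cultures had carried their lentivirus for at least 2 weeks and the siRNA cultures were taken at 48 h, per the labels. The sgRNA controls carried the Cas9 vector without a guide. Total RNA was sequenced as lncRNA libraries in the siRNA set and both sgRNA sets, on the NovaSeq platform in the D4M.3A shRNA set and on the BGISEQ platform in the B16/F10 shRNA set, so that technique, library kind and provider overlap. The pairing of libraries comes from the cell line, the technique and the study's design text. The title of the D4M.3A shRNA control names the line as D4M.4A while its cell line label says D4M.3A, and that label was used. Over genes with a mean FPKM of at least 0.5 its correlation was 0.801 to 0.803 with the libraries of the other D4M.3A set and 0.628 to 0.796 with those of B16/F10. The highest of the latter were with the B16/F10 shRNA set (0.796 and 0.785), so library kind also weighs here. The pigment genes Pmel and Dct were at 0.46 and 0.12 FPKM in it, against at least 112.6 and 137.7 in B16/F10. The column headings of 3 silenced libraries (B16/F10 shRNA and both sgRNA sets) carry another construct number than their treatment labels, so no construct number is given here.

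The authors aligned reads with STAR 2.4.0i and counted them with featureCounts 1.5.0-p1 on GRCm38.p6, per the submitters' processing notes. The gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. The authors deposited FPKM values (fragments per kilobase of gene length, scaled to sequencing depth), with 2 decimals, for 55276 genes named by symbol, beside each gene's length. Multiplying a low value by the gene's length gave whole multiples of a constant step in each library: among genes of length up to 400 and multiples up to 15, 98.8% to 100.0% of values were whole within the rounding of the deposited decimals. The step implied 48.9 to 54.9 M fragments in the 6 lncRNA libraries and 21.7 to 23.6 M in the 4 shRNA libraries. Of these, 79.5% to 84.1% and 48.4% to 49.7% were assigned to genes. The rounding of the deposited values amounted to a median of 0.33 to 0.75 reads per gene, so the values were kept as FPKM and no count model was run. Exact (Clopper-Pearson) 95% intervals of a ratio between 2 libraries were taken from reads estimated in this way. They cover counting error only, since reads copied by PCR are not independent molecules. Genes were matched to an NCBI RefSeq table of GRCm38.p6 for coordinates and biotype: 38896 by symbol, 250 by synonym, and 16130 had no match. Near-identical copies (Ifit3 and Ifit3b, the Apol9 and Prl2c families, histone genes) and overlapping genes (Ifi27 and Ifi27l2a) can share reads, so their values are uncertain.

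The log2 of FPKM plus a pseudocount of 1 was analysed, which understates the change of genes with low values. Over the 5 sets, genes with a mean FPKM of at least 0.5 (14240 genes) were tested with limma 3.58.1 (eBayes with trend, two-sided, set as a block), with Benjamini-Hochberg adjustment and a threshold of 0.05. The block is the main design. Libraries of a set deviated together from their group means (correlations of 0.885 to 0.964), and each silenced library matched its own control best. Interaction terms in the same model compared the change between B16/F10 and D4M.3A and between Cas9 and RNA interference. Before the data were examined, 24 gene lists, the tests, the alternative settings and the rule for named genes were written down. The lists were type I interferon response, interferon gamma type targets, nucleic acid sensing, MHC class I antigen presentation, interferons with chemokines and cytokines, NF-kappaB targets, 5'-3' and 3'-5' mRNA decay, nonsense mediated decay, snoRNA host genes, AU rich and immediate early mRNAs, integrated stress response, p53 targets, cell cycle, melanocyte lineage, mesenchymal state, hypoxia with glycolysis, cholesterol synthesis, replication dependent histones, cytosolic ribosomal proteins, mitochondrial mRNAs, and markers of fibroblasts, of macrophages with leukocytes and of keratinocytes with endothelium. Of 783 listed names, 3 were not found. Lists with at least 5 tested members were tested with limma's camera (correlation of 0.01), beside camera with an estimated correlation and fry, adjusted over the lists. A list's median change in each set was compared over the 5 sets by an exact two-sided sign-flip permutation test, whose smallest possible p is 0.0625.

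With 1 library per arm, a single set has no replicate check and no p-value. Genes that differed at least 2-fold were counted. A list's median was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Random lists take genes singly, so a list whose genes move together can reach an extreme percentile with a small median. Sets were compared by correlations of log2 changes across genes, which are not independent replicates, and by shared 2-fold genes beside the number that independent lists would share. The sets have no control library in common. The rule named Xrn1; the 10 largest mean rises and falls over the 5 sets among genes passing the test, filled where fewer pass by protein-coding genes with mean FPKM of at least 1 that moved the same way in 5 sets; the 5 largest rises and falls of each set among protein-coding genes with FPKM of at least 1 in a library; the 4 members of each list with the largest mean change; and the 5 largest differences per direction among genes passing an interaction. Other genes are said to have been chosen after their values were seen.

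The tests were tested on simulated data. With 200 genes changed equally in the 5 sets, limma recovered 85.4% of tested 2-fold changes and 84% of 4-fold changes, with 7 false calls among 14206 genes. With changes varying between sets by an SD of 0.5 of the fold, it recovered 36.7% and 51.6%, with 3 false calls among 14201 genes. For an interaction of 4-fold in B16/F10, it recovered 86% of 200 genes, with 11 false calls. With no list changed, 0 lists passed camera. With the interferon list raised 1.5-fold, 2 lists passed, and the interferon list had an adjusted p of 5.8e-79. Simulated genes varied independently, with noise of a fixed size that was not estimated from the data. These runs therefore do not test camera on lists whose genes move together, and the recovery holds for that noise only. Alternatives were other pseudocounts (0.1, 5), other filters (none, mean FPKM of at least 5), TPM, median-ratio or quantile scaling, no block, other eBayes settings, each set left out, and the B16/F10 or the lncRNA sets alone. Restriction to protein-coding genes, omission of the B16/F10 shRNA and sgRNA sets, and similarity without interferon genes were added after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used. The labels do not say that sets come from cultures grown apart in time, so p-values measure the spread between these sets.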

Results

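RNA sequencing was used to ask which genes change in mouse melanoma cells when Xrn1, the main cytoplasmic exoribonuclease that degrades decapped RNA from the 5' end, is silenced, with the innate immune response as the stated interest of the study. D4M.3A is a melanoma line with low levels of pigment gene transcripts in these libraries, and B16/F10 is a pigmented melanoma line. Of the 10 libraries, 4 came from D4M.3A (1 silenced and 1 control library by shRNA, 1 and 1 by sgRNA) and 6 from B16/F10 (1 and 1 each by siRNA, shRNA and sgRNA). The values deposited implied 48.9 to 54.9 M (mega) fragments in the 6 siRNA and sgRNA libraries, of which 39.7 to 46.1 M lay in genes, and 21.7 to 23.6 M in the 4 shRNA libraries, of which 10.7 to 11.6 M lay in genes. Between 20945 and 24140 genes had a value above 0 in a library. Across genes, the correlation of log2 values was 0.981 to 0.991 within a set, 0.797 to 0.990 between sets of the same line and 0.628 to 0.802 between lines. The 6 siRNA and sgRNA libraries contained non-polyadenylated RNA: 2 genes that overlap ribosomal RNA repeats (Gm26917 and Gm42418) took 11.7% to 15.6% of assigned reads there against 0.05% to 0.09% in the shRNA libraries, and the small nuclear RNA gene Rn7sk had 1523 to 2186 FPKM against 0.54 to 4.61. All changes below are silenced minus control in log2(FPKM + 1), and SDs are over the 5 sets (n = 5, with 1 library per arm in each set).

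Xrn1 mRNA was lower than in the control in 4 of the 5 sets, and in the fifth, the B16/F10 sgRNA set, it was not lower. Xrn1 lies on chromosome 9, 95954750 to 96057806 (GRCm38.p6). In D4M.3A it measured 0.89 FPKM with the shRNA and 1.51 FPKM in its control, which is 59.0% of control (exact 95% interval 51.9% to 66.9%). With the sgRNA it measured 2.97 against 3.57 FPKM, or 83.2% (79.2% to 87.3%). In B16/F10 it measured 1.61 against 2.94 FPKM with the siRNA, or 54.7% (51.4% to 58.2%), and 0.82 against 1.05 FPKM with the shRNA, or 78.1% (67.5% to 90.3%). The library labelled sgXrn1 of B16/F10 had 3.24 FPKM and its control 3.14 FPKM, or 103% (98.2% to 108%). A guide can disrupt the protein without lowering the mRNA, and protein was not measured in these data. Statements below that Xrn1 was not lower in that library refer to its mRNA only and leave the protein open. Over the 5 sets the mean change was -0.27 (SD 0.24, SE 0.10, limma adjusted p = 0.750; exact two-sided sign-flip p = 0.125, where 0.0625 is the smallest possible).

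**Figure D1:**
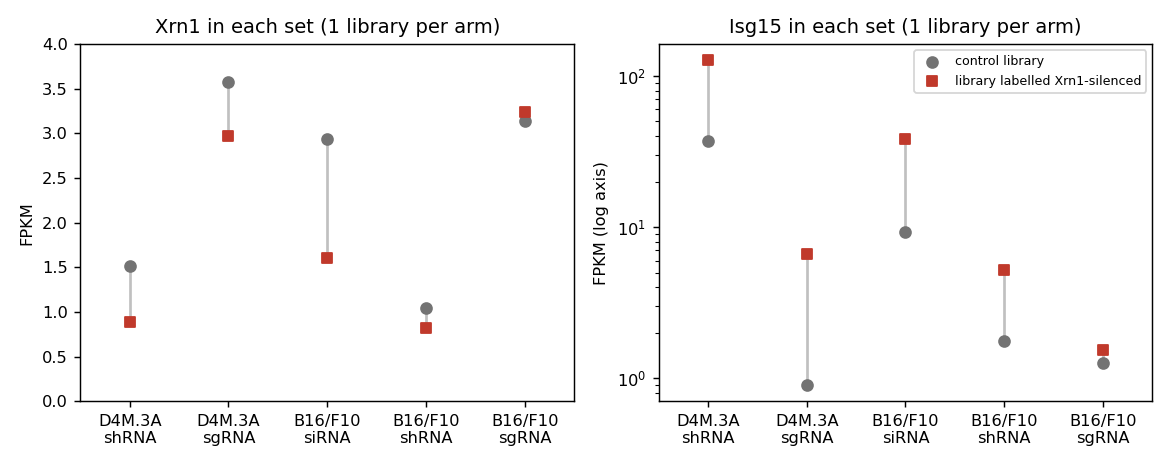
FPKM of Xrn1 and of the interferon-stimulated gene Isg15 in the silenced and the control library of each of the 5 sets (1 library per arm), on a linear axis for Xrn1 and a log axis for Isg15. Xrn1 is lower in the silenced library of 4 sets and at 3.24 against 3.14 FPKM in the B16/F10 sgRNA set, and Isg15 is higher in the library labelled as silenced of all 5 sets.

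Genes induced by type I interferon, which encode antiviral effectors and their regulators, were higher in the silenced libraries of both lines, most in both D4M.3A sets and the B16/F10 siRNA set. The 5 sets include the library labelled sgXrn1 of B16/F10, in which Xrn1 was not lower and the differences were among the smallest. Of 73 listed genes, 62 were tested, 49 of them were higher in all 5 sets, and 57 passed limma adjusted over the list alone, all upward. The list's median change was 0.88 in D4M.3A shRNA, 0.93 in D4M.3A sgRNA, 0.72 in B16/F10 siRNA, 0.20 in B16/F10 shRNA and 0.24 in B16/F10 sgRNA, each at percentile 100 of 10000 expression-matched random lists. The mean of the medians was 0.59 (SD 0.35; exact two-sided sign-flip p = 0.0625, the smallest possible). The list passed camera with the preset correlation (adjusted p = 3.2e-53) and did not pass with an estimated correlation of 0.66 (adjusted p = 0.268) or by fry (adjusted p = 0.0726; 0.0431 for changes in either direction). Isg15, a ubiquitin-like protein conjugated during antiviral responses (chromosome 4, 156199424 to 156200818), went from 36.9 to 126.9 FPKM in D4M.3A shRNA, 0.90 to 6.66 in D4M.3A sgRNA, 9.25 to 38.1 in B16/F10 siRNA, 1.77 to 5.18 in B16/F10 shRNA and 1.26 to 1.53 in B16/F10 sgRNA, a mean change of 1.40 (SD 0.77, SE 0.26, adjusted p = 0.372 over all genes and 0.00333 over the list alone). Usp18, which removes Isg15 from proteins (chromosome 6, 121245906 to 121270917), had a mean change of 1.26 (SD 0.77, adjusted p = 0.447 and 0.00512 over the list alone). Ifit3, an antiviral effector (chromosome 19, 34583119 to 34588982), had 1.18 (SD 0.70; 0.446 and 0.00477) and Rtp4 had 1.07 (SD 0.51; 0.372 and 0.00333). Ifit3 and its near-identical neighbour Ifit3b can share reads, so their values are uncertain.

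Over all genes, 0 of 14240 passed limma at an adjusted p of 0.05 (lowest adjusted p = 0.372). At an unadjusted p under 0.05 there were 883 genes, 670 higher and 213 lower, where chance gives about 1 in 20 of the genes tested. A total of 1084 genes (7.6%, where 6.25% would do so by chance) moved the same way in 5 of 5 sets, 809 up and 275 down, although Xrn1 was not lower in the library labelled sgXrn1 of B16/F10. The 10 largest mean differences upward among protein-coding genes of the same direction in 5 sets, none of which passed over all genes, were Isg15, Usp18, Ifit3, Apol9b (1.07, SD 0.92), Rtp4, the guanylate-binding protein Gbp3 (1.02, SD 0.70), the RNA sensor Ddx58 (0.96, SD 0.39, adjusted p = 0.372), the interferon regulatory factor Irf7 (0.96, SD 0.66), Prl2c2 (0.95, SD 0.76) and Ifit3b (0.95, SD 0.78). Reads of Apol9b and Prl2c2 can come from near-identical relatives. Without the B16/F10 shRNA and sgRNA sets, an omission chosen after the data were seen, 1 gene passed: Isg15 (1.90, adjusted p = 0.0456). The sets left out had the smallest medians of the type I interferon list (0.205 and 0.237), so this omission favours interferon-induced genes.

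**Figure D2:**
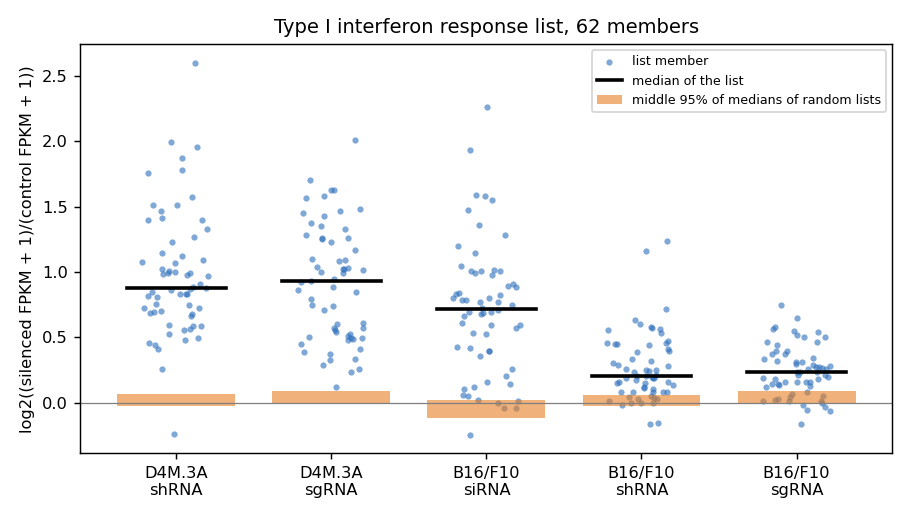
Silenced minus control log2(FPKM + 1) of the 62 tested genes of the type I interferon list in each of the 5 sets. Points are genes, black lines the list median, and bands the middle 95% of medians of matched random lists. The median is 0.88, 0.93 and 0.72 in the D4M.3A shRNA, D4M.3A sgRNA and B16/F10 siRNA sets. It is 0.20 and 0.24 in the B16/F10 shRNA set and in the sgRNA set, where Xrn1 mRNA was not lower in the library labelled sgXrn1.

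Targets of interferon gamma and many, though not all, genes of MHC class I presentation were also higher in the silenced libraries, and so were those sensors of foreign or misplaced nucleic acid that interferon itself induces. As for the type I list, differences were larger in D4M.3A than in B16/F10, and the library labelled sgXrn1 of B16/F10, where Xrn1 was not lower, had small ones. The nucleic acid sensing list (25 of 31 genes tested, 9 of them shared with the type I interferon list) had medians of 0.29, 0.28, 0.12, 0.12 and 0.13 in the sets in the order above (mean 0.19, SD 0.09, camera adjusted p = 1.0e-09; adjusted p = 0.223 with an estimated correlation, 0.0504 by fry and 0.0249 by fry in either direction), and 10 genes passed adjusted over the list alone, all upward. Of these, 8 are also on the type I interferon list, and the others, chosen after their values were seen, are Rnf135 (0.32) and Mlkl (0.38). The 16 sensing genes not on the type I list had medians of 0.09, 0.15, -0.06, 0.06 and 0.08, and the adaptors Mavs (-0.09) and Tmem173 (-0.21), also chosen after their values were seen, did not pass. Ddx58 (RIG-I; chromosome 4, 40203777 to 40239825) went from 3.74 to 8.43, 1.61 to 6.73, 8.95 to 18.8, 1.05 to 2.37 and 2.16 to 3.59 FPKM (adjusted p = 0.00522 over the list alone). Irf7 (0.96, 0.0121 over the list alone), the oligoadenylate synthetase Oas1a (0.88, 0.0269) and the RIG-I-like receptor Dhx58 (0.70, 0.00522) followed. The interferon gamma list (9 of 27 tested) had medians of 0.69, 0.84, 0.37, 0.12 and 0.26 (mean 0.46, SD 0.30, camera adjusted p = 2.2e-08; 0.223 with an estimated correlation, 0.0504 by fry, 0.0249 in either direction), and 6 genes passed over the list alone, led by the interferon-inducible GTPases Gbp2 (0.90, 0.00127), Irgm2 (0.80), Igtp (0.73) and Irgm1 (0.50; adjusted p = 0.00475 each). The MHC class I list (20 of 24 tested, 2 shared with the type I list) had medians of 0.58, 0.63, 0.18, 0.12 and 0.05 (mean 0.32, SD 0.27, camera adjusted p = 7.7e-08; 0.406 with an estimated correlation, 0.244 by fry, 0.0612 in either direction), with 10 genes up and 1 down adjusted over the list alone. The gene that went down was the peptide-loading chaperone Pdia3 (-0.17, adjusted p = 0.0442 over the list alone, lower in 5 of 5 sets), and the chaperones Canx (-0.14, lower in 5 sets) and Calr (-0.13, lower in 4 sets) did not pass; these 3 were chosen after their values were seen. Its largest were H2-T23 (0.69, 0.0442), the peptide-loading factor Tapbp (0.53, 0.0125), the immunoproteasome subunit Psmb10 (0.52, 0.0429) and the peptide transporter Tap1 (0.51, 0.0367). H2 genes resemble each other and can share reads. The medians of these lists lay at percentiles of 98.5 to 100 (sensing), 93.6 to 100 (interferon gamma) and 80.6 to 100 (MHC class I) of matched random lists.

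The next lists cover secreted mediators and stress responses. The list of interferons, chemokines and cytokines (11 of 41 tested) had a mean of 0.09 (SD 0.08, camera adjusted p = 0.0586; 0.0420 without the D4M.3A sgRNA set and 0.0386 without the B16/F10 sgRNA set). It passed with TPM (0.0352), median-ratio (0.0237) and quantile (0.0332) scaling. It also passed with a pseudocount of 0.1 (0.0331), without a filter (0.00895) and in the B16/F10 sets alone (0.0499), so the call depends on these settings. Under the main settings, camera with an estimated correlation gave an adjusted p of 0.334. In this list, 0 genes passed limma over the list alone (2 at an unadjusted p under 0.05): Ccl5 had a mean of 0.54 (adjusted p = 0.0786), Csf1 0.45, Cxcl10 0.38 and Cxcl11 0.19. Targets of NF-kappaB (21 tested) had a mean of 0.04 (SD 0.08, adjusted p = 0.120; 0.0376 without the D4M.3A shRNA set, 0.00535 without a filter, 0.0167 without the block and 0.00893 in the lncRNA sets alone). Of these, 1 gene passed over the list alone, the autophagy receptor Sqstm1 (0.35, 0.0198), while the protease Plau had -0.45, Nfkbiz 0.36 and Irf1 0.25. Targets of p53 (25 tested) had a mean of 0.12 (SD 0.12, camera adjusted p = 8.3e-05; adjusted p = 0.334 with an estimated correlation, 0.0249 by fry in either direction). Its median was -0.06 in D4M.3A shRNA (percentile 1.15 of matched lists) and 0.10 to 0.23 in the other 4 sets. In all, 5 genes passed over the list alone, all upward: the kinase Plk2 (0.47, 0.0115), the apoptosis gene Bbc3 (0.32, 0.0373), Tap1, which is shared with the MHC class I list, and, chosen after their values were seen, Bax and Sesn2. The cell cycle inhibitor Cdkn1a had 0.40. The integrated stress response list (32 tested) had a mean of 0.10 (SD 0.14, camera adjusted p = 0.00491; adjusted p = 0.614 with an estimated correlation, 0.285 without the B16/F10 siRNA set and 0.106 without the B16/F10 shRNA set), with a negative median in D4M.3A sgRNA (-0.14) and positive ones in the other 4 sets. Its largest were the cystine transporter Slc7a11 (0.64), Ddit3 (0.56), Chac1 (0.38) and Atf5 (0.37). AU-rich and immediate early mRNAs (37 tested) had a mean of 0.09 (SD 0.11, camera adjusted p = 0.0270; adjusted p = 0.614 with an estimated correlation, 0.546 without the B16/F10 siRNA set and 0.147 without the B16/F10 sgRNA set), with Ccn1 at 0.66, Ccn2 at 0.61, Nr4a3 at -0.46 and Fosl2 at 0.45. In both of these lists 0 genes passed limma over the list alone, with 9 genes at an unadjusted p under 0.05 in each.

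Pigment-cell genes were lower in the silenced B16/F10 cultures, and several members of the mesenchymal list (Thbs1, Acta2, Tagln and Fn1) were higher. These cultures include the library labelled sgXrn1, in which Xrn1 mRNA was not lower. In D4M.3A, pigment transcripts were near 0 in silenced and control libraries alike. The melanocyte lineage list (22 of 28 tested) had medians of -0.01 and 0.01 in D4M.3A and of -0.50, -0.41 and -0.10 in B16/F10 (percentiles of 0, 0 and 0.02; mean over 5 sets -0.20, SD 0.24, camera adjusted p = 1.5e-07; adjusted p = 0.334 with an estimated correlation). Pmel, which forms the fibrils on which melanin is laid down (chromosome 10, 128695888 to 128720238), measured 339 against 939 FPKM in B16/F10 siRNA, 113 against 297 in shRNA and 577 against 753 in sgRNA. Dct, an enzyme of melanin synthesis, measured 242 against 533, 138 against 240 and 363 against 502 FPKM. Bace2 had a mean of -0.50 and Rab27a, which moves melanosomes, -0.45. The mesenchymal list (33 of 42 tested) had a mean of 0.04 (SD 0.09, camera adjusted p = 0.0113; adjusted p = 0.600 with an estimated correlation, 0.106 without the B16/F10 siRNA set and 0.163 without the B16/F10 shRNA set), with Thbs1 at 1.20, Acta2 at 0.66, Tagln at 0.64 and Fn1 at 0.60. Its medians were -0.03 and -0.04 in D4M.3A and 0.02, 0.19 and 0.08 in B16/F10 (percentiles of 94.5, 100 and 96.3). In the B16/F10 siRNA, shRNA and sgRNA sets 18, 24 and 26 of the 33 members were higher. The cell cycle list (46 tested) had a mean of -0.07 (SD 0.21, camera adjusted p = 7.9e-05; adjusted p = 0.614 with an estimated correlation). Histone genes (43 tested), copies of which can share reads, were almost absent from the 4 shRNA libraries (median 0.07 to 0.17 FPKM, against 81.1 to 173.0 in the other 6). Only 3 sets therefore measure them. Their medians were 0.17 in D4M.3A sgRNA, -0.63 in B16/F10 siRNA and -0.13 in B16/F10 sgRNA, where Xrn1 was not lower. With the shRNA sets, whose medians were 0, they had a mean of -0.12 (SD 0.30, adjusted p = 0.000594; adjusted p = 0.614 with an estimated correlation). Both rested on the B16/F10 siRNA set, with medians of -0.45 and -0.63. In that set the rRNA-like genes took 15.6% of assigned reads in the silenced library and 11.7% in the control. Without that set the mean of the medians was 0.02 for the cell cycle (adjusted p = 0.881) and 0.01 for histones (adjusted p = 0.941). Named members were E2f8 (-0.19), Kif23 (-0.19), Ccnb2 (-0.18) and Ccne1 (0.17) for the cell cycle, and H4c3 (-0.24), H2ac10 (-0.23), H3c3 (-0.22) and H3c15 (-0.21) for histones. In these 4 lists 0 genes passed limma over the list alone, and at an unadjusted p under 0.05 there were 6 melanocyte, 8 mesenchymal, 1 cell cycle and 2 histone genes.

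**Figure D3:**
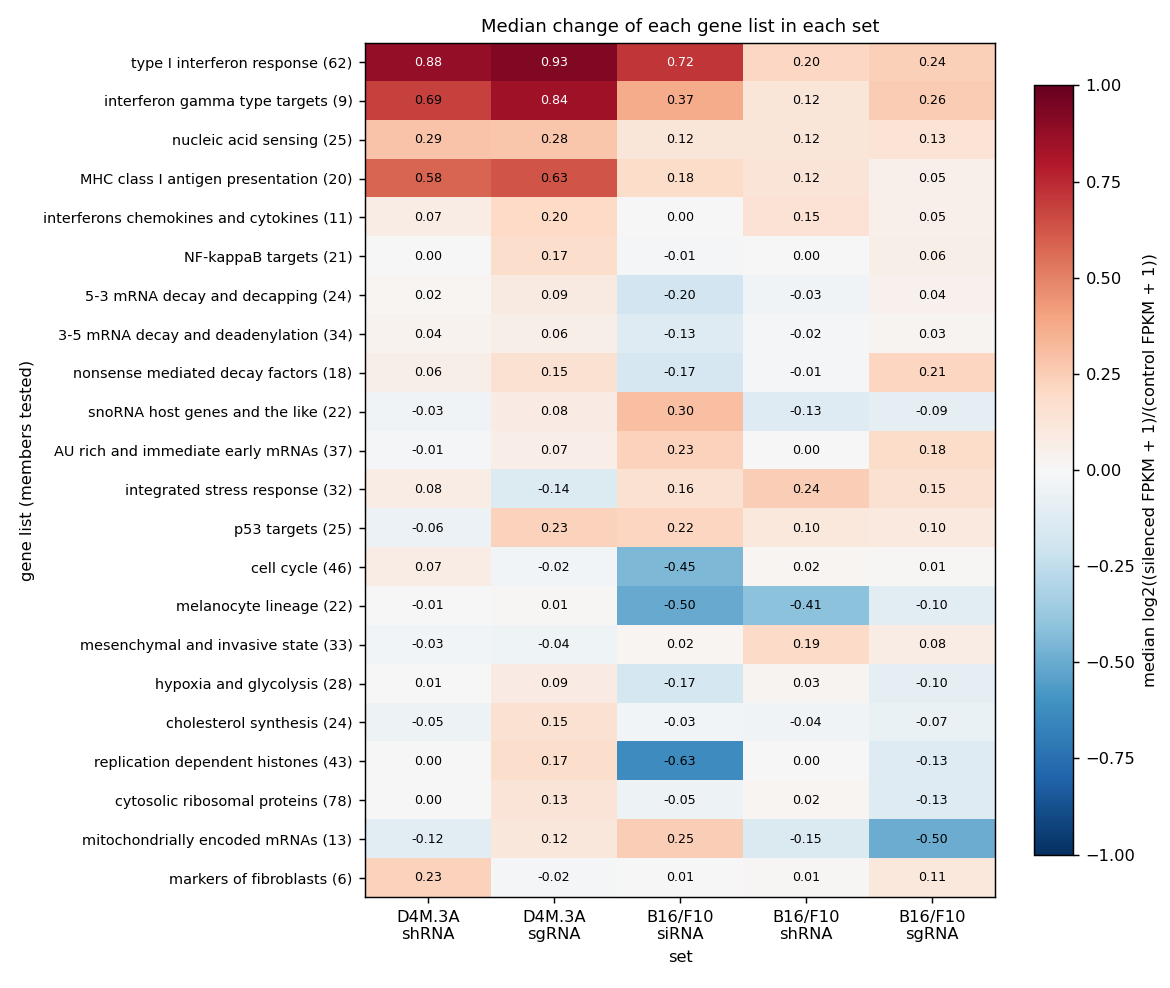
Median silenced minus control log2(FPKM + 1) of each of the 22 tested gene lists (vertical) in each of the 5 sets (horizontal), as colours with the value printed. The type I interferon list is positive in each set, from 0.20 to 0.93, and the melanocyte list is at -0.50, -0.41 and -0.10 in the B16/F10 sets. Xrn1 mRNA was not lower in the library labelled sgXrn1 of B16/F10.

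The lists for the RNA decay machinery did not pass camera with the 5 sets together. Factors of 5'-3' decay (24 tested) had a mean of -0.01 (SD 0.11, camera adjusted p = 0.272), with Dcp2, the decapping enzyme, at 0.25, Ddx6 at 0.21 and Dxo at -0.15. Factors of 3'-5' decay (34 tested) had -0.01 (SD 0.08, 0.272), with Btg2 at 0.15, Cnot8 at -0.08, Ttc37 at 0.08 and Exosc2 at 0.08. Nonsense mediated decay factors (18 tested) had 0.05 (SD 0.15, 0.226; 0.0104 without the B16/F10 siRNA set), with Smg1 at 0.25, Dhx34 at 0.18, Upf3b at 0.16 and Smg5 at 0.14. Host genes of snoRNAs (22 tested) had 0.03 (SD 0.17, 0.472; -0.04 and 0.0496 without the B16/F10 siRNA set), with Snhg15 at 0.34, Epb41l4aos at 0.32, Snhg17 at 0.32 and Snhg9 at -0.29. Hypoxia and glycolysis genes (28 tested) had -0.03 (SD 0.10, 0.116; 0.0114 without the D4M.3A sgRNA set), with Adm at 0.33, Egln1 at -0.18, Egln3 at -0.15 and Hk1 at 0.15. Cholesterol synthesis genes (24 tested) had -0.01 (SD 0.09, 0.135; 0.00485 without that set), with Insig1 at -0.19, Hsd17b7 at 0.15, Dhcr7 at -0.13 and Mvk at 0.12. Cytosolic ribosomal protein genes (78 tested) had -0.01 (SD 0.09, 0.143; 4.1e-05 without that set), with Rpl10a at 0.14, Rpl32 at -0.09, Rpl27a at -0.09 and Rps12 at 0.08. Mitochondrially encoded mRNAs (13 tested) had -0.08 (SD 0.29, 0.0561; 0.0299 without that set and 7.5e-06 without the B16/F10 siRNA set), with mt-Cytb at -0.20, mt-Co2 at -0.17, mt-Nd2 at -0.16 and mt-Nd4l at 0.13, and a median of -0.50 in B16/F10 sgRNA. Fibroblast markers (6 tested) had 0.07 (SD 0.10, 0.312), with Col1a1 at 0.27, Pdgfrb at 0.19, Pdgfra at 0.09 and Col6a3 at -0.08. Too few members were tested for macrophage and leukocyte markers (4 tested; mean of medians -0.07, SD 0.14; Laptm5 -0.36, Cd68 -0.05, Cd14 0.03, Csf1r -0.01) and for keratinocyte and endothelial markers (1 tested, Vwf, at -0.08). In each list with at least 5 tested members in this paragraph, 0 genes passed limma over the list alone, with 0 to 4 genes per list at an unadjusted p under 0.05. Some of these lists passed under other settings: snoRNA hosts in the lncRNA sets alone (0.00158), hypoxia (0.0176) and cholesterol synthesis (0.00983) in the B16/F10 sets alone, ribosomal proteins there (2.1e-05) and with median-ratio scaling (0.0204), and mitochondrial mRNAs with a pseudocount of 5 (0.0379) and with TPM (0.0352). Of the 22 lists tested, 11 passed camera with the preset correlation (8 up, 3 down), 0 with an estimated correlation and 0 by fry, or 4 by fry in either direction. The signs of some set medians flip with the scaling of the libraries in the NF-kappaB, 5'-3' and 3'-5' decay, cell cycle, hypoxia, cholesterol, ribosomal and fibroblast lists. A median of 0 became 0.037 with median-ratio scaling for cytokines in B16/F10 siRNA, and 0.001 with quantile scaling for histones in D4M.3A shRNA.

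The largest mean differences downward in the same direction in 5 of 5 sets were small, and none passed over all genes. The 5 sets include the library labelled sgXrn1 of B16/F10, in which Xrn1 mRNA was not lower. The genes were Bace2 (-0.50, SD 0.58, adjusted p = 0.784, near 0 FPKM in D4M.3A), the proteoglycan Gpc1 (-0.44), the matrix protein Fbln1 (-0.40, at 0.46 FPKM or less in D4M.3A), the protease Prss12 (-0.39, SD 0.18, adjusted p = 0.420), Sema7a (-0.39, near 0 FPKM in B16/F10), Sparcl1 (-0.36), Syngr1 (-0.35), Chsy3 (-0.35, near 0 FPKM in D4M.3A), the glycosyltransferase Mgat5 (-0.33) and Oxld1 (-0.32).

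A further comparison asked whether the change after silencing differs between the lines. Medians of the interferon-related lists were higher in D4M.3A, and those of the stress, immediate early and mesenchymal lists in B16/F10, whose 3 sets include the library labelled sgXrn1, in which Xrn1 mRNA was not lower. The only siRNA set, taken at 48 h, and the only BGISEQ set are both B16/F10, so line cannot be told apart from technique, time and platform. The type I interferon median was 0.72 in B16/F10 siRNA, 0.20 in B16/F10 shRNA and 0.24 in B16/F10 sgRNA. By limma 0 of 14240 genes passed (lowest adjusted p = 0.200). At an unadjusted p under 0.05 there were 873 genes, 471 more positive in B16/F10 and 402 more negative, where chance gives about 1 in 20 of the genes tested. With a pseudocount of 5, 2 genes passed, Cxcr4 and Nefl, chosen after their values were seen, and among protein-coding genes alone 12 passed. By camera 11 lists differed with the preset correlation and 0 with an estimated correlation. The type I interferon list had a mean of 0.39 in B16/F10 and 0.90 in D4M.3A (adjusted p = 2.1e-23; adjusted p = 0.298 with an estimated correlation) and MHC class I 0.12 and 0.61 (adjusted p = 3.8e-12; adjusted p = 0.0915 with an estimated correlation). Thbs1 differed by 2.47 (adjusted p = 0.305).

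Cas9 editing and RNA interference were compared in the same way, and the type I interferon list had like means of its set medians with both (0.58 and 0.60). The sets of each technique lay far apart: 0.93 and 0.24 with Cas9, and 0.88, 0.72 and 0.20 with RNA interference. The likeness of the means therefore does not show that both techniques gave the same response. Xrn1 mRNA was not lower in the library labelled sgXrn1 of B16/F10, which makes 1 of the 2 Cas9 sets. By limma 0 genes passed (lowest adjusted p = 0.704). At an unadjusted p under 0.05 there were 651 of 14240 genes, which is under the 1 in 20 that chance gives. Of these, 451 were more positive with Cas9 and 200 more negative. By camera 8 lists differed with the preset correlation and 0 with an estimated correlation, and the type I interferon difference was -0.02 (adjusted p = 0.0286; adjusted p = 0.988 with an estimated correlation).

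Taken singly, the sets have no replicate check and no p-value, and the counts below mix real differences with noise. In the D4M.3A shRNA set, interferon-induced genes were the most raised protein-coding genes: Ifi27l2a (2.60, from 2.67 to 21.2 FPKM, at a locus overlapping Ifi27), Gbp3 (1.99), Ifit3 (1.96), Ifit3b (1.87) and Irf7 (1.78). The most lowered were the keratin Krt20 (-1.83), the acetylcholine receptor subunit Chrna1 (-1.68), the neurofilament Nefl (-1.51), Igfbp3 (-1.40) and the growth factor Areg (-1.40). Among all genes 89 were at least 2-fold higher and 94 lower. Among 10886 protein-coding genes the counts were 40 and 20, and 26 of those 40 belong to the interferon lists.

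In the D4M.3A sgRNA set the most raised protein-coding genes were Apol9b (2.20), the prolactin-family gene Prl2c2 (2.17), Isg15 (2.01), Usp18 (1.70) and Rtp4 (1.63). The lowest were Mgp (-1.84), an inhibitor of calcification, Akr1c18 (-1.52), Dmp1 (-1.51), the matrix gene Smoc2 (-1.45) and the ion channel Trpa1 (-1.38). Of all genes 68 were at least 2-fold higher and 47 lower. Of protein-coding genes 40 were higher and 20 lower, and 29 of those 40 belong to the interferon lists.

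In the B16/F10 siRNA set, taken at 48 h, the matrix glycoprotein Thbs1 (2.65; chromosome 2, 118111876 to 118127133; 6.19 to 44.1 FPKM) stood beside Usp18 (2.26), the kinase Prkg2 (2.15), the GTPase Rhob (1.94) and Isg15 (1.93). The lowest were Tspan10 (-2.23), Mylpf (-2.08), the receptor Epha3 (-2.04), the lipase Mgll (-1.99) and the exchanger Slc24a4 (-1.82). Of all genes 149 were at least 2-fold higher and 61 lower, and of protein-coding genes 83 and 36, with 16 of the 83 in the interferon lists.

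The B16/F10 shRNA set showed Thbs1 (2.43, 5.13 to 32.1 FPKM), the matricellular gene Ccn2 (1.61), Cdsn (1.35), Ifi27 (1.24, at a locus overlapping Ifi27l2a) and Serpinf1 (1.21) as the most raised. The most lowered were hormone and granule genes of pancreatic islets: Ins2 (-4.44, 333.9 FPKM in the control and 14.4 in the silenced library), Ins1 (-4.33, 157.6 and 6.86), Iapp (-3.70, 35.7 and 1.82), Gcg (-3.12, 13.1 and 0.62) and Chga (-2.95, 9.80 and 0.40). Ins2 was listed at 0 in the other 8 libraries, and digestive enzyme genes of the exocrine pancreas were present in the same control library (Cela2a 2.49, Prss2 2.21 and Cpa1 1.05 FPKM, chosen after their values were seen). Of all genes 64 were at least 2-fold higher and 67 lower, and of protein-coding genes 14 and 12, with 2 of the 14 in the interferon lists.

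**Figure D4:**
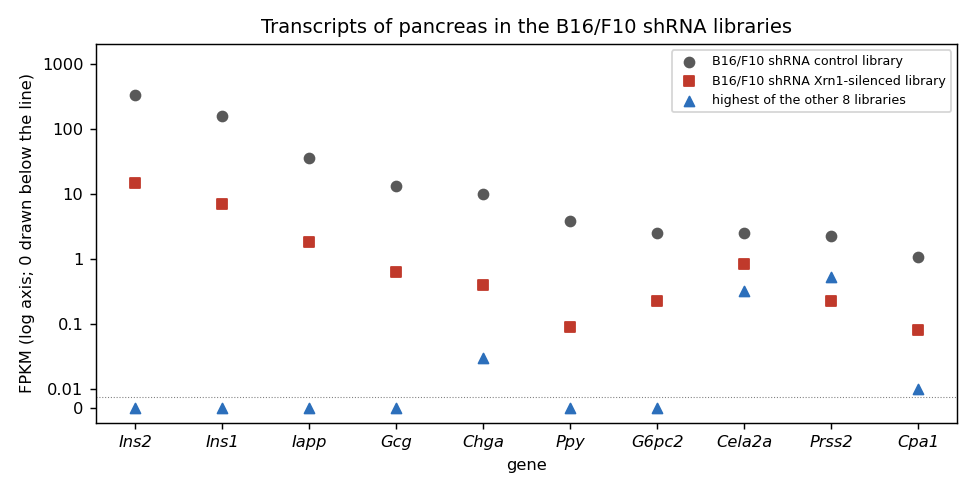
FPKM (log axis) of pancreatic genes in the B16/F10 shRNA control library, its silenced library, and the highest of the other 8 libraries. Ins2 is at 333.9 FPKM in the control and 14.4 FPKM in the silenced library.

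In the B16/F10 sgRNA set, where Xrn1 was not lower in the library labelled sgXrn1, the most raised were the junction-associated Amotl2 (1.80), the lectin Clec2d (1.60), 2900026A02Rik (1.56), Thbs1 (1.49, 5.67 to 17.8 FPKM) and Slc7a11 (1.25). The most lowered were the mitochondrial leucyl-tRNA synthetase Lars2 (-1.19), Cd68 (-0.61), Gm10197 (-0.58), Pin4 (-0.49) and the melanosome gene Oca2 (-0.48). Of all genes 39 were at least 2-fold higher and 80 lower. When each library was rescaled to the same total (TPM) these counts became 141 and 160. Of protein-coding genes 12 were higher and 1 lower, with 0 of the 12 in the interferon lists.

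**Figure D5:**
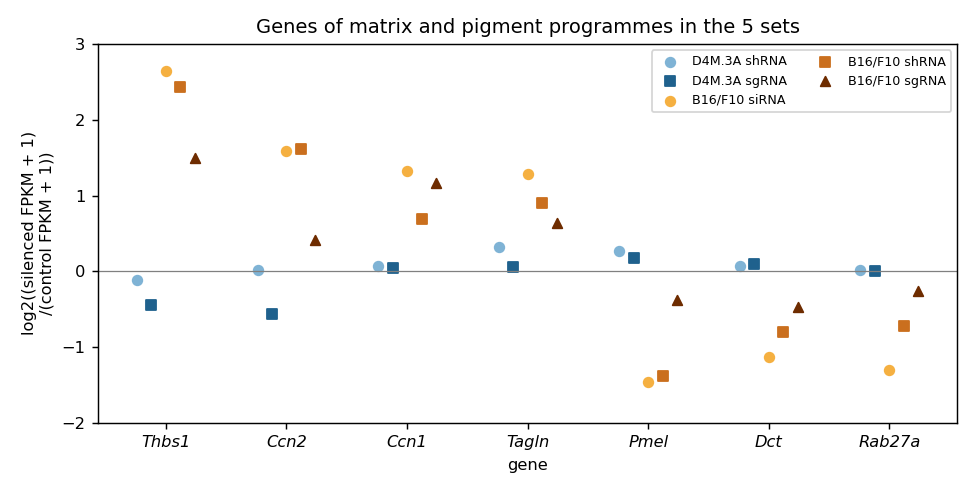
Silenced minus control log2(FPKM + 1) of matrix genes (Thbs1, Ccn2, Ccn1), the contractile gene Tagln and pigment genes (Pmel, Dct, Rab27a) in each of the 5 sets. Thbs1 is at 2.65, 2.43 and 1.49 in the B16/F10 sets and at -0.12 and -0.44 in the D4M.3A sets. Xrn1 mRNA was not lower in the library labelled sgXrn1 of B16/F10.

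The sets were then compared for likeness, with correlations across genes, which are not independent replicates. Over all genes the 10 pairs of sets had a mean Pearson correlation of 0.075 (range -0.004 to 0.203), and over protein-coding genes 0.147, highest for both D4M.3A sets (0.371, Spearman 0.181). Those shared 20 raised genes where independent lists would share 0.15, and 7 lowered genes against 0.04. The B16/F10 siRNA and shRNA sets followed (0.295, Spearman 0.220), with 7 shared raised genes against 0.11. Across lines, D4M.3A shRNA and B16/F10 siRNA shared 12 raised genes against 0.30 (correlation 0.054), and D4M.3A sgRNA and B16/F10 siRNA 14 against 0.30 (correlation 0.078). Without the genes of the interferon lists the correlation was 0.279 for the D4M.3A sets (2 shared raised genes against 0.01) and 0.278 for B16/F10 siRNA and shRNA (6 against 0.07). For D4M.3A shRNA and B16/F10 siRNA it was then -0.027 (0 shared raised genes against 0.09), and for D4M.3A sgRNA and B16/F10 siRNA -0.002 (3 against 0.07).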

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

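The tests of library kit and of the size of the Xrn1 loss, and the restriction to protein-coding genes, were chosen only after the results were seen. Values that stand apart from the other sets were found for 3 of 43 items, where chance gives 1 in 20, or about 2.1. The cell cycle list had a median of -0.45 in the B16/F10 siRNA set and -0.02 to 0.07 in the other sets. Fbln1, a matrix protein, had -1.05 in that set and -0.32 to -0.07 in the others. In D4M.3A it was at 0.46 FPKM or less and could hardly fall on this scale. The cholesterol synthesis list had 0.15 in the D4M.3A sgRNA set and -0.07 to -0.03 in the others.

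The change after silencing differed between the lines for 11 lists by camera with the preset correlation, and for 0 with an estimated correlation. Line cannot be told apart here from technique, time and platform, since the only siRNA set and the only BGISEQ set are both B16/F10. In B16/F10, the library labelled sgXrn1 showed no lower Xrn1 mRNA, and protein was not measured. B16/F10 minus D4M.3A was -0.52 for type I interferon (adjusted p = 2.1e-23; adjusted p = 0.298 with an estimated correlation), -0.52 for interferon gamma targets (0.000644; 0.298), -0.16 for nucleic acid sensing (0.00799; 0.418) and -0.49 for MHC class I (3.8e-12; 0.0915). It was 0.11 for AU-rich and immediate early mRNAs (3.1e-05; 0.461), 0.21 for the integrated stress response (3.1e-07; 0.140) and 0.13 for the mesenchymal list (6.0e-06; 0.204). It was -0.16 for the cell cycle (0.00505 and 0.794) and -0.12 for ribosomal proteins (3.7e-06 and 0.794). For histones, which the shRNA sets hardly measure, it was -0.34 (0.000320 and 0.794). For the melanocyte lineage it was -0.34 (0.000108 and 0.550). Pigment transcripts were near 0 in D4M.3A and could hardly fall there, so this value mainly restates the fall in B16/F10.

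Between Cas9 and RNA interference, 8 lists differed with the preset correlation and 0 with an estimated correlation, with adjusted p of 0.919 to 0.988 there. The library labelled sgXrn1 of B16/F10, in which Xrn1 mRNA was not lower, makes 1 of the 2 Cas9 sets. Cas9 minus RNA interference was -0.018 for type I interferon (adjusted p = 0.0286), 0.12 for NF-kappaB targets (0.0122), 0.14 for 5'-3' decay (0.0122), 0.22 for nonsense mediated decay (0.00303), -0.15 for the integrated stress response (0.0138), 0.26 for the melanocyte lineage (0.0122), -0.044 for the mesenchymal list (0.0138) and -0.19 for mitochondrial mRNAs (0.0122).

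Other splits of the 10 libraries were run for the gene tests. The real split gave 0 genes, so each of the 100 splits drawn from 126 gave as many by construction (100 of 100, the highest other 125), and this count says nothing about chance. The splits with many genes were those that part only the B16/F10 siRNA pair (125 genes), which points to a structure of the samples: that pair differs more than the others. Splits that part only the B16/F10 shRNA pair gave up to 8 genes, only the sgRNA pair 1, and only a D4M.3A pair 0. All 16 splits that part 5 pairs, as the real one does, gave 0 genes. For each interaction the real count was 0 and the highest other 0, and all 10 of 10 splits gave as many, again by construction; these splits are also too few for a share under 0.05.

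The smaller interferon response in the B16/F10 shRNA and sgRNA sets (medians of 0.20 and 0.24 against 0.72 to 0.93) was weighed. Compression of low values by the pseudocount is argued against as the whole account: with a pseudocount of 0.1 the higher of both medians was 0.42, or 47.8% of the lowest of the other 3 (0.88). Whether it plays a part stays open. From a pseudocount of 1 to 0.1, the B16/F10 shRNA median went from 0.205 to 0.422 and the sgRNA median from 0.237 to 0.326. The D4M.3A shRNA, D4M.3A sgRNA and B16/F10 siRNA medians went from 0.88, 0.928 and 0.717 to 1.149, 1.586 and 0.882. A library kit effect alone is argued against for the sgRNA set, whose median lay 0.480 below the lowest of the other sets with lncRNA libraries, and cannot be told apart for the shRNA set, the only one from the BGISEQ platform (0.675 below the D4M.3A shRNA set, which came from another platform and provider). A smaller loss of Xrn1 may play a part and cannot be told apart: the D4M.3A sgRNA median exceeded that of B16/F10 shRNA by 0.723 with Xrn1 mRNA at 83.2% and 78.1% of control, but the intervals overlap. In the library labelled sgXrn1 of B16/F10 Xrn1 mRNA was not lower. After a guide the mRNA level does not give the loss of the protein, which was not measured. Cell line, time after silencing and reagent stay open and were not tested apart.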

How the results depend on the processing

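Restriction to protein-coding genes, omission of the B16/F10 shRNA and sgRNA sets (left out because of Xrn1 mRNA not being lower and because of pancreatic transcripts) and similarity without interferon genes were chosen after seeing the data. The median of the type I interferon list stayed positive under all settings run (0.29 to 0.87), and Xrn1 stayed negative (-0.41 to -0.11, with no value at a mean FPKM of at least 5). With each set left out in turn, the count of genes stayed at 0, that of lists went from 9 to 16, both interactions stayed at 0, Xrn1 went from -0.34 to -0.19 and the interferon list from 0.51 to 0.69. Without the B16/F10 shRNA and sgRNA sets, which had the smallest interferon medians, 1 gene passed, from fewer sets, and the cause was not tested. The line interaction had 2 genes with a pseudocount of 5 and 12 among protein-coding genes alone, where the model was fitted anew on fewer genes. The cause was not tested for either. With an estimated correlation 0 lists passed, and 0 by fry; the interferon list (0.59) then had an adjusted p of 0.268 and 0.0726, its genes being correlated at 0.66. At an unadjusted p under 0.05 there were 405 to 1340 genes over the settings with the block. Without the block 0 genes passed (10 at an unadjusted p under 0.05) and 10 lists, the interferon adjusted p being 4.1e-81; the melanocyte (0.0584) and histone (0.170) lists no longer passed and NF-kappaB did (0.0167). Reversals were found for snoRNA hosts (-0.042, adjusted p = 0.0496; up to 0.066 with another set left out), the cell cycle (0.019, 0.881) and histones (0.011, 0.941) without the B16/F10 siRNA set, and for the mesenchymal list (-0.015, 0.476) without the B16/F10 shRNA and sgRNA sets; the cause was not tested. Calls were lost for AU-rich mRNAs without the B16/F10 siRNA (0.546) or sgRNA (0.147) set and with a pseudocount of 5 (0.0822), for the integrated stress response without the B16/F10 siRNA (0.285) or shRNA (0.106) set, and for the mesenchymal list without the siRNA (0.106) or shRNA (0.163) set or without a filter (0.0539). AU-rich mRNAs (0.0744) and the integrated stress response (0.436) also lost theirs without the B16/F10 shRNA and sgRNA sets. Calls were gained in 26 cases, among cytokines, NF-kappaB, decay, snoRNA host, hypoxia, cholesterol, ribosomal and mitochondrial lists. Counts of 2-fold genes in D4M.3A shRNA, D4M.3A sgRNA, B16/F10 siRNA, shRNA and sgRNA moved from 183, 115, 210, 131 and 119 to 572, 474, 687, 519 and 440 with a pseudocount of 0.1, to 19, 13, 54, 15 and 11 with a pseudocount of 5, which compresses low values, to 47, 46, 105, 38 and 41 at a mean FPKM of at least 5 (fewer genes), to 481, 304, 471, 435 and 301 with TPM, where values are 3.42 to 5.40 times larger and the pseudocount weighs less, and to 60, 60, 119, 26 and 13 among protein-coding genes, which are fewer. In the B16/F10 sgRNA set TPM put the median of all genes at 0.11 (0.04 as deposited). Mean similarity was 0.049 to 0.147. The rounding to 2 decimals limits genes of low expression.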

Other observations

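The tests of an off-target effect and of fibroblasts in the sgRNA set and the choice of Thbs1, Ccn2 and the genes named in this part were made only after the results were seen. Genes driven by actin and serum response factor were higher in the silenced B16/F10 cultures, among them the myosin light chain Myl9 and the actin-binding Tmsb4x. Myl9 measured 64.2 against 17.7 FPKM in the siRNA set, 103.0 against 52.6 in the shRNA set and 27.3 against 18.1 in the sgRNA set, whose library labelled sgXrn1 had no lower Xrn1. Tmsb4x measured 112.7 against 36.4, 123.2 against 58.1 and 56.8 against 50.4 FPKM. A list of such genes, without Acta2, Tagln and Myl9, which had been seen (20 genes left), had medians of 0.50, 0.26 and 0.13 in the B16/F10 sets (percentiles of 100, 100 and 99.9 of matched lists), and of 0.21 and -0.01 in D4M.3A shRNA and sgRNA (percentiles of 100 and 7.25).

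Among pigment genes of B16/F10, the enzyme Tyrp1 measured 1125 against 1882 FPKM with the siRNA, 574.5 against 823.5 with the shRNA and 1431 against 1652 with the sgRNA. The pigment enzyme Tyr was near 0 throughout, at 0.02 against 0.05, 0.02 against 0.03 and 0.07 against 0.15 FPKM. The transcription factor Mitf measured 47.3 against 87.8, 17.4 against 22.7 and 68.0 against 70.5 FPKM, and Sox10 63.0 against 68.2, 98.3 against 101 and 68.4 against 69.0. In the sgRNA set Xrn1 mRNA was not lower in the library labelled sgXrn1. The interferon gene Ifnb1 was at 0 to 0.10 FPKM in all 10 libraries.

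For the pancreatic transcripts of the B16/F10 shRNA control library, silenced to control ratios of the 8 genes seen first lay between 0.0295 (Sst) and 0.0885 (Ctrb1), but those of Chgb (0.203), Cela2a (0.331), Ctrl (0.438), Ctrc (0.559) and Cela1 (0.856) were higher. Of these, Cela1, Ctrl, Ctrc and Cela2a were at up to 1.83, 0.45, 0.39 and 0.32 FPKM in the other 8 libraries and at 1.69, 0.58, 0.90 and 0.82 FPKM in the silenced library, and such a baseline raises a ratio, while Chgb was at no more than 0.03 and at 0.19 FPKM. Of 51 further pancreas genes detected, 40 (78.4%, exact 95% interval 64.7% to 88.7%) were highest in that library, consistent with RNA or reads of pancreatic tissue there. Of 27 exocrine genes detected, which islet cells lack, 22 (81.5%, 61.9% to 93.7%) were highest there, which argues against an islet programme of the melanoma cells. Their levels were low: the 35 exocrine genes listed summed to 19.17 FPKM in that library, where Ins2 was at 333.94. Some of these calls rest on few reads, such as Amy2b and Sycn with 2 each, and others on more, such as Cela2a with 93. Which part of the pancreas such RNA would come from was not tested. Where such RNA would have entered stays open.

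Thbs1 and Ccn2, higher in the silenced B16/F10 cultures, were weighed, with Xrn1 mRNA not lower in the library labelled sgXrn1. Fibroblasts are argued against in the siRNA and shRNA sets, where the largest rise of 5 fibroblast genes was 0.234, and stay open in the sgRNA set, where Col1a2 was higher by 0.624 (0.33 to 1.05 FPKM) and Col1a1 by 0.16, while Col3a1, Dcn and Lum were listed at 0. Both genes were higher by at least 1.585 with the siRNA and with the shRNA, and with the sgRNA Thbs1 was higher by 1.49 and Ccn2 by 0.41. This argues against an effect of 1 reagent alone only if the siRNA and the shRNA differ in sequence, which was not checked. An off-target effect common to both stays open. Higher activity of YAP and TEAD may contribute, which percentiles cannot decide. A list of their targets without Thbs1 and the Ccn genes lay at a percentile of at least 99.63 in the B16/F10 sets. Of its 17 genes, Amotl2, Axl and Igfbp3 had been seen. The 14 genes not seen lay at 96.0, 99.8 and 99.7 with the siRNA, shRNA and sgRNA, with medians of 0.07, 0.16 and 0.18. The same 14 genes lay at 96.9 and 3.69 in D4M.3A shRNA and sgRNA. In D4M.3A shRNA, Thbs1 changed by -0.12 and Ccn2 by 0.01. Genes of a list can move together, unlike those of random lists. Ribosomal protein genes lay at 100 in D4M.3A sgRNA (median 0.13) and at 0 in B16/F10 sgRNA (-0.13).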
